A study of Mus musculus with 4 samples.

How the data were processed

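The deposited values are whole-number UMI counts per gene and barcode, in filtered 10x matrices of 32285 genes made from mouse lung at postnatal day 8. Per the labels' protocols, lungs were dissociated, stained for CD45, EpCAM and CD31, sorted into 4 compartments and run with the 10x Chromium 3' v3 chemistry, with 3 mice per genotype pooled into 1 sort. Per the submitters' processing notes, the counts of the authors involve Cell Ranger 4.0.0, Seurat 4 and the mm10 build, with no role given for each. The gene annotation behind the counts is not given in the sources used here. Gene positions come from the GENCODE annotation of the same build, matched by gene identifier. The 3 mice of a genotype cannot be separated in the files except in part by sex-linked transcripts.

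Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16. Barcodes with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept, 46893 of 49645. Simulated doublets were scored in each library and the highest scores removed at 0.8% per 1000 barcodes, which marked 777, 1048, 1874 and 961 cells in libraries 1 to 4. Each library was clustered separately on 2000 variable genes and 40 principal components with 20 neighbours, by the Leiden method at a resolution of 1.5. A cluster took the class whose fixed markers were highest in it, by a mean log2 excess of at least 0.7 over the other clusters with a pseudocount of 10 CPM and at least 3 markers raised at least 2-fold.

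Clusters stayed unnamed with a median under 1500 UMIs, with over 75% doublet calls, with under 30 cells, with no marker of the class among the 10 genes of highest fold, or where no class led. Those below the UMI limit held 1681, 1772, 6186 and 1584 cells of libraries 1 to 4, mostly doublet clusters 228, 291, 558 and 246, clusters led by no class 0, 547, 365 and 125, and small clusters 62, 19, 0 and 66. In all 30209 cells were named, without called doublets; sizes of named clusters leave these out and sizes of unnamed clusters include them. A class was counted only in the library of each genotype that held its compartment, which left out 92 and 222 cells with endothelial names in libraries 1 and 3, 137 with a mesenchymal name in library 1 and 74 with the AT2 name in library 4. The last name rested on 3 markers in a cluster led by Fabp4 and Vwa1, and Epcam or Cdh1 was found in 0.157% of the cells of that library, so these cells are not taken as epithelial. Myofibroblast and smooth muscle clusters were merged into 1 class because their markers overlapped. The separate clustering, the doublet rate, these naming limits and the merger were set after the data were seen. The cell type markers, the 15 gene lists, the rule for named genes and the other settings were fixed before the data were examined.

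Counts were summed over the cells of a class, and the 10 classes that were listed for comparison in advance and had at least 30 cells per genotype were compared. Another 8 classes had that many cells but were not on that list, and genes of some of them are in the closing section. Genes kept by the expression filter of edgeR at a minimum count of 10 were scaled by its TMM factors, and CPM values within classes are on these scaled totals, while CPM over all cells of a library are on plain totals. The log2 ratio of the TMM factors, mutant over control, which is taken off the log2 ratio of each gene, was -0.75 in neutrophil-like, -0.15 in interstitial macrophage-like, -0.12 in monocyte-like and 0.20 in T cell-like cells, and under 0.1 in size in the other 6 classes. Each CPM carries an exact Poisson interval, each share an exact Clopper-Pearson binomial interval and each fold an exact interval from the 2 counts, all at 95% and covering counting error only. A fold against a count of 0 was computed against a floor of 3 counts over the class as a bound.

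Tests were planned with the quasi-likelihood method, DESeq2 and camera, with the 2 libraries of a genotype as replicates, together with a chi-square test between these libraries and a test of shares. The libraries of a genotype held different compartments, so no class had a replicate and none of these tests could be run. The planned rule for that case was used: values with intervals, and genes named by size. Named genes were the 5 highest and 5 lowest by log2 ratio among genes at least 2-fold apart, with a mean of at least 30 CPM and at least 5% of the level in the class where the gene is highest, leaving out sex-linked, mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, unnamed gene models and markers of the class; 2 genes are not reported here. The rule also named Nlrp3, Lyz2, Il1b, Il18, Tnf and Ifng whatever their values, with up to 4 members of each list at least 2-fold apart, to which the abundance limits were applied after the data were seen. Nlrp3, Lyz2, Il1b, Il18, Tnf and Ifng are given over all cells of libraries 1 and 3, and only in part within classes. Genes of interest outside this rule are named in the closing section and were chosen after their values were seen.

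The lists cover the inflammasome and IL-1 family, TNF and NF-kB response, interferon-gamma response, type I interferon response, chemokines and acute phase, elastic fibre assembly, collagen and other matrix, contractile apparatus, angiogenesis and VEGF signalling, surfactant and lipid synthesis, the injury-associated alveolar epithelial state, cell division, hypoxia and glycolysis, p53 targets and apoptosis, and immediate early and heat shock genes. Counts of list members cover all measured members, and the percentile of a list median is its place among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists were drawn gene by gene and do not carry the shared regulation of list members, so a percentile is a rank and no test between genotypes. Some genes are on more than 1 list. RNA from neutrophils, AT2 cells, fibroblasts and endothelium in other classes was traced by S100a8 and S100a9, Sftpc, fibrillar collagen genes, and Cldn5, Egfl7, Cdh5 and Pecam1. On simulated data from gCap-like sums of 13237 genes, 100% of genes altered 2.5-fold or 4-fold in either direction were found at least 2-fold apart, and 0% of 5025 unchanged genes. From neutrophil-like sums of 12470 genes, 98% of genes raised 2.5-fold and 100% of the other sizes were found. Of 40 random lists 7.5% and 5% fell outside the middle 95%. No class had a replicate, so these rates cover counting error and not the spread between libraries.

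Other settings fixed in advance were RLE scaling, all genes with at least 1 count, stricter limits on cells (800 genes, 500 for neutrophils, and 5% mitochondrial UMIs), doublets kept, counts thinned to equal totals and a resolution of 0.75. Added after the data were seen were subtraction of free RNA, mutant cells with Y transcripts and no Xist, mutant cells with Xist and no Y transcripts, clusters with a median of at least 900 UMIs named, and no scaling beyond totals.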

Results

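Single-cell transcriptomes were compared at postnatal day 8 between lungs of control mice and lungs of mice that carry a mutant Nlrp3 allele together with LysM-Cre. This Cre acts in myeloid cells, and whether it acts in these alone was not tested. Nlrp3 encodes the sensor of an inflammasome, a complex that activates caspase-1 and so the cytokines IL-1β and IL-18, and the series title links its overactivity to IL-18, TNF and the building of the gas exchange surface. Immune, epithelial, endothelial and mesenchymal cells were sorted and mixed again in set proportions, with 3 mice per genotype pooled into 1 sort. There were 2 libraries per genotype. Control library 1 held 97605232 UMIs in 10427 barcodes, control library 2 held 87109675 in 12338, mutant library 3 held 171389387 in 15556 and mutant library 4 held 79411728 in 11324. Median UMIs per barcode were 5740, 5696.5, 2127 and 5762.5.

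Libraries 1 and 3 held immune and epithelial cells, and libraries 2 and 4 held endothelial and mesenchymal cells. Ptprc, the CD45 gene, was at 369 CPM in library 1 and 579 CPM in library 3, against 1.18 CPM in library 2 and 5.25 CPM in library 4. The summed collagen and PDGF receptor genes of the mesenchyme were at 6824 CPM in library 2 and 4570.3 CPM in library 4, against 81.8 CPM and 16.0 CPM in libraries 1 and 3. Each class of cells was therefore measured in 1 library per genotype, so no difference below has a replicate check and no test between genotypes was made. Intervals are 95% and cover counting error only. A difference between genotypes cannot be told apart from a difference between 2 libraries, and the female transcript Xist was at 0.456 and 0.129 CPM in control against 183.9 and 677.5 CPM in mutant libraries.

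Neutrophil-like cells were the most numerous immune class in the mutant, with shares of 13.9% (12.8 to 14.96) of control and 60.9% (59.5 to 62.2) of mutant immune cells named. Alveolar macrophage-like cells made up 26.3% (25.01 to 27.7) of control and 14.8% (13.9 to 15.9) of mutant immune cells. Monocyte-like cells made up 11.9% (10.97 to 12.97) of control and 3.03% (2.57 to 3.54) of mutant immune cells, and T cell-like cells made up 15.7% (14.6 to 16.9) of control and 10.3% (9.43 to 11.1) of mutant immune cells. B cell-like cells were 613 of 4153 control immune cells and 0 of 5052 in the mutant, with an upper limit of 0.0730%. At least 3 UMIs of the B cell genes Cd79a, Cd79b and Ms4a1 were found in 11.1% of 9015 cells of library 1 and 0.409% of 13189 cells of library 3. Shares of interstitial macrophage-like cells were 9.73% and 9.05%, with intervals that overlapped. The shares of a compartment add up to the whole, so a larger neutrophil-like share by itself lowers the other immune shares. Cells named were 576 and 3075 neutrophil-like, 1094 and 750 alveolar macrophage-like, 404 and 457 interstitial macrophage-like and 653 and 518 T cell-like, in control and mutant. Among immune cells other than neutrophil-like cells, the shares of the last 3 classes were higher in the mutant. Those of monocyte-like, dendritic cell-like and type 2 innate lymphoid-like cells stayed lower. Dendritic cell-like cells were 3.44% in control and 1.31% in the mutant, and cells like type 2 innate lymphoid cells were 3.106% and 0.653%. The dendritic ratio, mutant over control, was 0.379, and it was 0.711 with doublets kept, while coarser clusters named 0 mutant cells, for a bound of 0.0160. Mast cell or basophil-like cells were 45 of 4153 in control, and in the mutant a cluster of 66 cells led by Tpsb2 and Mcpt4 was left unnamed for low UMIs, so the count of 0 named cells is set by that limit.

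Among named endothelial cells, gCap-like cells (general capillary cells) made up 72.4% (70.7 to 74.1) of control and 47.96% (46.6 to 49.3) of mutant cells, and aCap-like cells (aerocytes, the capillary cells of the thin gas exchange barrier) made up 8.14% (7.16 to 9.22) of control and 17.98% (16.97 to 19.03) of mutant cells. Arterial-like cells were 7.47% and 19.6%, venous-like cells 8.89% and 5.06%, and lymphatic-like cells 3.06% and 9.43%, in control and mutant. Of the mutant arterial-like cells 671 came from a cluster led by Esm1 that matched the markers less well, and the other 393 alone made up 7.23%. Among named mesenchymal cells, alveolar fibroblast-like cells were 21.2% (20.05 to 22.3) of control and 33.4% (31.6 to 35.3) of mutant cells, and myofibroblast or smooth muscle-like cells were 56.8% (55.5 to 58.2) of control and 49.7% (47.8 to 51.6) of mutant cells. Pericyte-like cells were 9.54% and 4.82%, adventitial fibroblast-like cells 9.48% and 12.04%, and mesothelial-like cells were 153 of 5114 in control, with 0 of 2657 named in the mutant because its cluster of 67 cells led by Slpi and Msln was called doublets throughout, while a control cluster with 64.8% doublet calls was kept. AT2-like cells, the surfactant-making cells of the alveolus, were 95.9% and 97.9% of named epithelial cells and ciliated-like cells 4.09% and 2.06%. The ciliated ratio of 0.504 was 0.245 with low UMI clusters named and 0.809 with doublets kept, and only the control cluster was led by the secretory genes Scgb1a1, Scgb3a2 and Cyp2f2. The sort set the compartments, and low UMI clusters left unnamed held 41.1% of the cells of library 3 against 17.2% in library 1, 15.8% in library 2 and 14.6% in library 4. With those clusters named, the ratio of alveolar macrophage-like shares, mutant over control, was 1.005 in place of 0.564; the adventitial ratio was 0.974 with stricter limits on cells and 2.17 with coarser clusters in place of 1.27, and the interstitial macrophage ratio was 0.587 with doublets kept in place of 0.930.

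**Figure D1:**
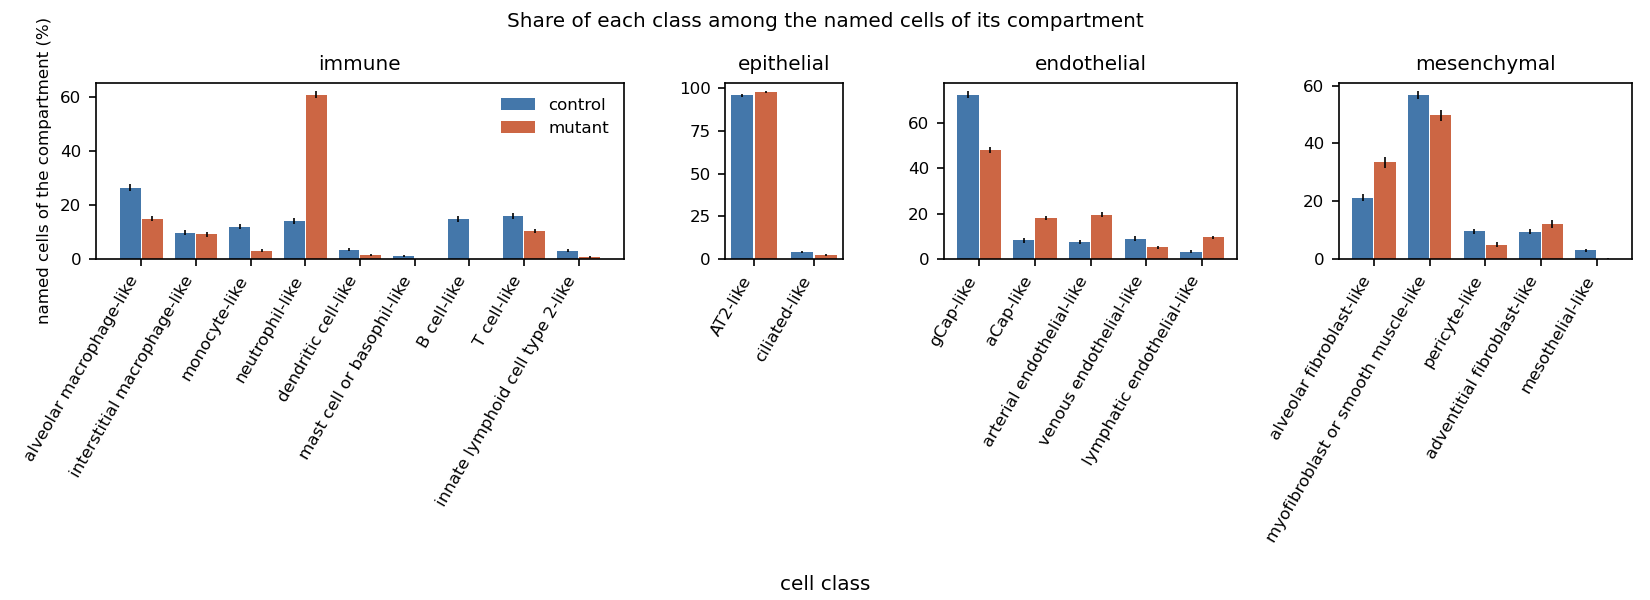
Share of each class among the named cells of its compartment, in percent on a linear axis, with control in blue and mutant in orange and exact 95% binomial intervals as error bars. Neutrophil-like cells stood at 13.9% in control and 60.9% in the mutant, and gCap-like cells at 72.4% and 48.0%.

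Nlrp3 itself (ENSMUSG00000032691, chromosome 11 from 59541568 to 59566956 of mm10) was at 23.5 CPM over all cells of library 1 and 112.5 CPM in library 3, and at 1.06 and 1.91 CPM in libraries 2 and 4. The mutation is a base change, so these levels do not check the genotype labels. Nlrp3 was higher in the mutant in alveolar macrophage-like cells by 2.80-fold (interval 2.55 to 3.07), in interstitial macrophage-like cells by 4.30-fold (interval 3.70 to 4.99), in monocyte-like cells by 4.31-fold (interval 3.59 to 5.18) and in neutrophil-like cells by 2.16-fold (interval 1.91 to 2.44), or 1.28-fold on plain totals. Lyz2 (ENSMUSG00000069516, chromosome 10 from 117277331 to 117282321), whose promoter drives Cre in this strain, was at 5910 CPM in library 1 and 2219 CPM in library 3. On plain totals Lyz2 was at 7794 CPM in control AT2-like and 5918 CPM in control alveolar macrophage-like cells, so Cre may not be confined to myeloid cells, which was not tested. Tnf (ENSMUSG00000024401, chromosome 17 from 35199381 to 35202007) was at 41.5 and 206 CPM, Il1b (ENSMUSG00000027398, chromosome 2 from 129364570 to 129371139) at 220.1 and 1243 CPM, and Il18 (ENSMUSG00000039217, chromosome 9 from 50554827 to 50581840) at 62.4 and 38.1 CPM in libraries 1 and 3. These levels over all cells also depend on the mix of cells, which differed. On plain totals Il1b was 1.01-fold and Tnf 4.02-fold in neutrophil-like cells, mutant over control. In alveolar macrophage-like cells Il1b was at 344 and 531 CPM in control and mutant. There Il18 was at 313 and 368 CPM, while it was lower in mutant neutrophil-like cells. Ifng (ENSMUSG00000055170, chromosome 10 from 118441046 to 118445892), the gene of interferon-γ, was at 1.03 CPM in library 1 and 0.375 CPM in library 3, with 99 and 64 UMIs.

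Tnf was higher in mutant alveolar macrophage-like cells, at 153 CPM in 1094 control cells and 785 CPM in 750 mutant cells, or 5.13-fold (interval 4.88 to 5.40). Nfkbiz and Nfkbia, which NF-kB induces, were 9.33-fold and 5.03-fold higher, and the neutrophil chemokine gene Cxcl1 was 5.79-fold higher. Of the TNF and NF-kB response list, 11 of 25 measured members were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.54 at percentile 100 of 10000 random lists. Il18 differed little, with a log2 ratio of 0.16, while Il1b stood at 0.55, Il1a at 1.17 and Casp4 at 1.07.

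Among the genes with the highest ratios in these macrophages were Lrg1 at 79.9-fold (interval 50.9 to 133), Ifitm1 at 52.2-fold (interval 43.6 to 63.2) and the eosinophil-associated ribonuclease gene Ear6 at 24.9-fold (interval 19.9 to 31.7). After subtraction of free RNA the log2 ratio of Ifitm1 was 4.43 in place of 5.71. Adamdec1 went from 983 UMIs in control to 0 in the mutant, at least 262-fold lower against a floor of 3 UMIs, and the elastase gene Mmp12 was 51.99-fold (interval 31.4 to 93.2) lower. A cluster of 104 cells led by Adamdec1 and Mmp12 was found in control cells only. The chemokine receptor gene Ccr2 was 10.2-fold (interval 8.09 to 13.01) lower, Nr4a2 9.77-fold (interval 7.77 to 12.4) lower and Lyz2 4.80-fold (interval 4.71 to 4.89) lower. Immediate early genes were higher, 5 of 22 measured by at least 2-fold, with Egr1 at a log2 ratio of 1.94 and Jun at 1.56. The interferon-induced gene Ifi27l2a had a log2 ratio of -1.99 and Irf1 of 2.12. The cell division list had a median of -0.33 with 0 of 26 members 2-fold apart, and RNA traced to neutrophils took 0.164% of control and 3.35% of mutant UMIs in this class.

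In interstitial macrophage-like cells the antigen presentation genes of MHC class II were far lower in the mutant. H2-Eb1 was 51.5-fold (interval 36.96 to 73.97) lower, H2-Ab1 43.7-fold (interval 33.5 to 58.1) lower, H2-Aa 42.7-fold (interval 32.9 to 56.4) lower and the invariant chain gene Cd74 12.4-fold (interval 11.4 to 13.5) lower. The interferon-gamma response list, which holds these genes, had 8 of 26 members at least 2-fold higher and 6 lower (median 0.47). This median turned direction with mutant cells that had Y transcripts and no Xist. Retnla and Treml4 were lower by 34.9-fold (interval 16.8 to 87.02) and 15.9-fold (interval 7.98 to 37.1). Higher were Slfn4 and Olfm4, both also leading genes of mutant neutrophil-like clusters, at 178-fold (interval 96.1 to 373) and 75.6-fold (interval 56.9 to 103), the adhesion gene Vcam1 at 17.5-fold (interval 14.7 to 21.1), Cxcl1 at 8.45-fold (interval 6.88 to 10.4), Tnf at 2.86-fold (interval 2.54 to 3.23) and Il1b at 2.73-fold (interval 2.57 to 2.90). The inflammasome and IL-1 family had 9 of 18 measured members at least 2-fold higher, with a median log2 ratio of 1.04, and the cell division list had 23 of 26 members at least 2-fold lower, with a median of -1.89. Saa3, Lrg1 and Cd177 also stood among the 5 highest within the naming limits, at log2 ratios of 6.03, 5.91 and 5.78, but RNA traced to neutrophils made up 3.51% of control and 23.0% of mutant UMIs. After subtraction of free RNA Saa3 stood at -1.89 and Lrg1 at 0.46, and no level was left for Cd177 and Lcn2; median UMIs per cell were 9796 in 404 control cells and 2638 in 457 mutant cells, and 1 control cluster of the class had 53.9% doublet calls. Of the 2 mutant clusters 1 with 322 cells held S100a8 and S100a9 at 126140 CPM, Il1b at 1605 CPM and Tnf at 172 CPM on plain totals, and 1 with 135 cells held them at 9623 CPM, 503 CPM and 305 CPM, against 482 CPM, 242 CPM and 93.1 CPM in the control cluster of few doublets.

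In monocyte-like cells of the mutant Cx3cr1, Adgre4, Ldlrad3, Slc12a2 and Ifi27l2a were lower by 25.9-fold, 40.8-fold, 30.8-fold, 28.1-fold and 22.4-fold. Il1r2, the IL-1 decoy receptor gene, was 79.9-fold (interval 52.00 to 129.5) higher, Tnf 9.25-fold (interval 7.11 to 12.2), Gbp2 13.8-fold (interval 11.4 to 16.9) and Irf1 8.25-fold (interval 7.19 to 9.50). Of the interferon-gamma response list, 15 of 26 members were at least 2-fold higher and 4 lower (median log2 ratio 1.49), while 0 of 17 type I interferon genes were higher and 6 lower (median -0.72). Cell division genes were higher, 18 of 26, with a median of 1.61, Birc5 at 3.92 and Mki67 at 3.122. Lrg1, Saa3, Ifitm1, S100a9 and Cstdc4 had the highest log2 ratios within the naming limits, 8.79, 7.66, 7.62, 6.71 and 6.50. Control cells came from 1 cluster led by Ace, Treml4 and Eno3 and 1 led by Ly6c2 and Ccr2, and all 153 mutant cells from 1 cluster led by Vcan, Prtn3 and Ccr2, with 35.4% doublet calls and a median of 19937 UMIs per cell against 6838 in control. RNA traced to neutrophils by S100a8 and S100a9 made up 1.53% of control and 28.8% of mutant UMIs, which counts any such RNA made by monocytes themselves, and after its subtraction no level was left for Cstdc4 and Lcn2, Lrg1 stood at 6.80 and the ratio of Cxcl2 went from 3.48 to 1.65. Il1r2 and Tnf were at 736 and 181 CPM in mutant neutrophil-like cells on plain totals. Part of their ratios in monocyte-like cells may therefore come from neutrophil RNA.

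In neutrophil-like cells of the mutant Saa3 (ENSMUSG00000040026, chromosome 7 from 46711998 to 46715700), an acute phase gene, was 839.9-fold (interval 457 to 1752) higher. Nos2, which makes nitric oxide, was 335-fold (interval 60.03 to 13223) higher with 1 control UMI, the lipase gene Lipg 270.4-fold (interval 74.8 to 2234) higher with 2, the granule protease gene Prtn3 151-fold (interval 41.7 to 1245) higher with 2, and Ggt1 88.9-fold (interval 38.1 to 274) higher with 5. Tnf was 6.77-fold (interval 5.65 to 8.18) higher, Il1b 1.71-fold (interval 1.66 to 1.76) higher and Il1r2 10.2-fold (interval 9.14 to 11.4) higher, while Il18 was 3.40-fold (interval 2.55 to 4.47) lower and Lyz2 2.403-fold (interval 2.36 to 2.44) lower. On plain totals Il1b was at 1911 CPM in control and 1939 CPM in the mutant, or 1.01-fold, Tnf and Il1r2 were 4.02-fold and 6.05-fold higher, and Lyz2 and Il18 were 4.05-fold and 5.72-fold lower. The interferon-gamma response list had 16 of 28 members higher and 7 lower, among them Gbp2 at a log2 ratio of 3.98 and Irf8 at -3.64. Of hypoxia and glycolysis genes 10 of 19 were higher (median 1.14), with Hilpda at 3.02 and Gpi1 at 2.29, and of the inflammasome and IL-1 family 10 of 19 were higher, with Casp4 at 2.03 and Pycard at 1.93.

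Lower in mutant neutrophil-like cells were Adgre4 at 543-fold (interval 261 to 1361), Ace at 132-fold (interval 95.6 to 186), Eno3 at 71.7-fold (interval 53.6 to 97.7), Cbfa2t3 at 53.8-fold (interval 39.5 to 74.4) and Cx3cr1 at 48.04-fold (interval 40.5 to 57.3), genes of non-classical monocytes for the most part. The 576 control cells came from 2 clusters led by Ngp, Camp and Ltf and 1 led by Stfa1 and Retnlg, in which these monocyte genes were found. The 3075 mutant cells came from 6 clusters, 1 of them led by Mpo, Elane and Prtn3, genes of immature neutrophils, which gave 117 cells after removal of 50% as doublets. Median UMIs were 2646 and 10113 per cell. The scaling factors of this class differed by -0.75 on the log2 scale, which raised its ratios by that size, and without scaling the medians of the TNF and NF-kB, chemokine and cell division lists were -0.15, -0.10 and -0.30 in place of 0.61, 0.66 and 0.45.

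T cell-like cells of the mutant held more Il22, a cytokine gene of type 3 lymphocytes that acts on epithelium, at 71.2-fold (interval 27.5 to 263) with 4 control UMIs. Rasl11a was 117-fold (interval 45.6 to 432) higher, also with 4 control UMIs, and Serpina3f, Serpina3g and Ifitm1 were 26.6-fold, 22.9-fold and 19.6-fold higher. RNA traced to neutrophils rose from 0.262% of control to 3.71% of mutant UMIs, and after subtraction of free RNA the log2 ratio of Ifitm1 was 2.92 in place of 4.29 and that of Il1b 1.03 in place of 2.18. Receptor genes of IL-1 and IL-18 were higher: Il1r1 by 5.83-fold (interval 4.09 to 8.54), Il18r1 by 2.78-fold (interval 2.38 to 3.249) and Il18rap by 2.47-fold (interval 1.95 to 3.15). The inflammasome and IL-1 family as a whole had 10 of 17 measured members at least 2-fold higher (median 1.30), and the TNF and NF-kB response 10 of 23. Ifng was lower, at 18.02 CPM in control and 7.61 CPM in the mutant, 2.37-fold (interval 1.54 to 3.71). Ifi27l2a, Hist1h2af, Dapl1 and Sox4 were lower by 7.64-fold, 7.44-fold, 6.72-fold and 4.70-fold, and 9 of 26 cell division genes were at least 2-fold lower (median -0.79); control cells included a cluster of 156 cells with histone genes among its leading genes, and mutant cells none. Ly6d, which is on the B cell and plasmacytoid dendritic cell marker lists, was 648-fold (interval 179 to 5359) lower with 2 mutant UMIs. Mutant cells included a cluster led by Nrgn, Rasl11a and Serpina3g and 1 led by the γδ T cell genes Trdc and Trdv4. The NK cell marker genes Gzma, Nkg7 and Klrd1 were among the leading genes of 1 control cluster, as was Trdc, and Nkg7 among those of 1 mutant cluster.

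Cell division and type I interferon genes and 4 MHC class II genes were lower in AT2-like cells of the mutant, while the median of the surfactant list lay near 0. H2-Ab1 (ENSMUSG00000073421, chromosome 17 from 34257689 to 34269419) was at 451 CPM in 2742 control cells and 9.55 CPM in 1566 mutant cells, 47.2-fold (interval 41.6 to 53.8) lower, with H2-Eb1 30.4-fold (interval 26.9 to 34.4), H2-Aa 29.5-fold (interval 27.2 to 32.1) and Cd74 11.3-fold (interval 10.99 to 11.5) lower. The interferon-gamma response list, which holds these 4 genes, had 3 of 26 members at least 2-fold higher and 8 lower (median -0.22, percentile 8.23). The fibrillin gene Fbn2 was 34.05-fold (interval 25.6 to 46.3) lower and Top2a 22.3-fold (interval 17.7 to 28.6) lower. Of the cell division list 25 of 26 members were at least 2-fold lower and 0 higher (median -3.34), and of type I interferon genes 11 of 16 were lower and 1 higher (median -1.76). The median of the surfactant and lipid synthesis list was 0.015, at percentile 53.89 of random lists, and Lyz2, an AT2 gene in mice as well, stood at -0.53.

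Higher in AT2-like cells of the mutant were the transcription factor gene Zbtb16 at 16.9-fold (interval 14.2 to 20.2), Rgcc at 10.2-fold (interval 9.86 to 10.6), the proton pump gene Atp6v0a4 at 9.48-fold (interval 8.43 to 10.7), Gdpd2 at 9.36-fold (interval 8.44 to 10.4) and the sodium channel gene Scnn1a at 6.16-fold (interval 5.84 to 6.51). The acute phase genes Hp and Lcn2 had log2 ratios of 1.92 and 1.72. The TNF and NF-kB response had 9 of 26 measured members at least 2-fold higher and 0 lower (median 0.73), and the list of the injury-associated alveolar state had 4 of 16 higher (median 0.56), among them the cell cycle inhibitor gene Cdkn1a at 1.16. Hk2 stood at 1.495, Atf3 at 1.57 and the basement membrane collagen gene Col4a1 at -1.26. AT1-like cells formed only 1 cluster of 15 cells and were not compared; with coarser clusters 56 control cells (1.96%) and 0 mutant cells were named AT1-like. Median UMIs were 12835 in control and 15591.5 in mutant cells, and RNA traced to neutrophils made up 0.296% of control and 2.20% of mutant UMIs.

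In gCap-like cells interferon-γ response genes were higher across the list in the mutant, 26 of 28 measured members by at least 2-fold and 0 lower, with a median log2 ratio of 3.10 at percentile 100 of random lists. Ciita, the master regulator of MHC class II, was 86.8-fold (interval 41.9 to 216) higher, H2-Ab1 53.4-fold (interval 41.8 to 69.3), Gbp5 27.6-fold (interval 20.7 to 37.7) and Iigp1 24.3-fold (interval 22.6 to 26.1) higher, and MHC class II genes were among the leading genes of the mutant clusters of this class. Among genes within the naming limits, which leave out Cd74 and H2-Eb1 at log2 ratios of 8.18 and 8.16, Ch25h, Serpina3f, Serpina3g, Lrg1 and Igfbp3 had the highest ratios, 227-fold, 196-fold, 126-fold, 114-fold and 90.5-fold. Type I interferon genes were higher in 14 of 20 cases (median 1.41), with Ifit1 at 3.99, and TNF and NF-kB genes in 11 of 23 (median 0.93), with Csf1 at 3.27 and Icam1 at 2.08. Cdkn1a (ENSMUSG00000023067, chromosome 17 from 29090976 to 29100727) was at 104 CPM in 2037 control cells and 649 CPM in 2608 mutant cells, and the death receptor gene Fas stood at 1.98.

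Cell division genes were lower in gCap-like cells of the mutant, 19 of 26 by at least 2-fold with a median of -3.46. Nusap1 was 85.5-fold (interval 48.6 to 166) lower, Hist1h3c 60.5-fold, Hist1h1b 60.02-fold, Ube2c 41.8-fold and Birc5 36.3-fold lower. Control cells of the class included a dividing cluster of 339 cells, while a dividing mutant cluster of 125 cells was left unnamed, and with it added to the class the median was -0.56. Named mutant cells of the class included a cluster of 388 cells with Hells, Ccnd1 and the list member Mcm5 among its leading genes. Genes of the contractile apparatus (11 of 20 lower, median -1.52), elastic fibre assembly (9 of 19, -0.91) and collagen (9 of 28, -0.88) were lower as well. RNA traced to fibroblasts made up 2.65% of control and 1.02% of mutant UMIs, and the contractile median was -0.60 after subtraction of free RNA. Among angiogenesis genes Unc5b stood at -1.69, Aplnr at -1.24, Esm1 at 1.54 and Vegfc at 1.48, with a list median of 0.18.

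The aCap-like cells, 229 in control and 978 in the mutant, likewise held more interferon-γ response transcripts, 25 of 26 measured members at least 2-fold higher and 0 lower, with a median of 2.98. Lrg1 was 196-fold (interval 54.1 to 1616) higher and Gbp6 76.7-fold (interval 21.1 to 634) higher with 2 control UMIs each, and Clca3a1, Gbp2 and Nlrc5 were higher by 99.1-fold (interval 17.7 to 3922), 86.6-fold (interval 15.5 to 3430.2) and 62.2-fold (interval 11.1 to 2465) with 1 control UMI each. Serpina3n went from 0 to 758 UMIs, at least 54.2-fold higher. Cdkn1a was at 159 and 1329 CPM, 8.37-fold (interval 7.17 to 9.83) higher. Rtn1, Adam12, Gxylt2, Tnfrsf21 and Adam23 were lower by 16.03-fold, 13.3-fold, 13.02-fold, 12.2-fold and 10.99-fold. Apln, a ligand gene made by these cells, stood at -1.56 and Unc5b at -1.73. Type I interferon genes were higher in 12 of 16 cases, and the collagen list lower in 14 of 26 (median -1.09). The elastic fibre median of -0.86 was -0.08 after subtraction of free RNA and the collagen median -1.08 over 20 measured members, with RNA traced to fibroblasts at 2.88% of control and 1.18% of mutant UMIs of aCap-like cells.

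Alveolar fibroblast-like cells of the mutant held high levels of acute phase genes. Lcn2 (ENSMUSG00000026822, chromosome 2 from 32384633 to 32388252), which encodes an iron-scavenging protein, was 1982-fold (interval 678 to 9614) higher with 3 control UMIs, Hp 712-fold (interval 541 to 956), Saa3 329-fold (interval 271 to 402) and Serpina3n 262-fold (interval 176 to 408) higher. Scara5 was 464-fold (interval 82.99 to 18362) higher with 1 control UMI and Galnt15 302-fold (interval 103 to 1465) higher with 3. The chemokine and acute phase list had 17 of 19 members at least 2-fold higher (median 3.005), the TNF and NF-kB response 16 of 23 (median 1.98), the interferon-gamma response 19 of 25 (median 1.77) and type I interferon genes 12 of 17 (median 1.97). RNA traced to endothelium made up 0.969% of control and 1.87% of mutant UMIs of alveolar fibroblast-like cells, and after subtraction of free RNA these 2 medians were 1.45 and 2.03. Icam1 stood at 4.01, Csf1 at 2.58, Il1r1 at 2.28 and Cdkn1a at 3.92.

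Elastic fibre genes went both ways in these fibroblasts, with a list median of -0.034. Elastin, Eln, was at 2023 CPM in 1082 control cells and 11016 CPM in 888 mutant cells, 5.45-fold (interval 5.35 to 5.54) higher, the cross-linking enzyme gene Lox 7.30-fold (interval 6.85 to 7.78) and Fbn2 7.12-fold (interval 5.77 to 8.86) higher, while Fbln5, which places elastin on microfibrils, was 9.79-fold (interval 9.09 to 10.6) lower. Tenascin gene Tnc was 8.69-fold (interval 7.59 to 9.97) lower, and contractile genes were lower in 8 of 20 cases, with Acta2 at -2.75 and Myl9 at -2.45. Fabp3, Slitrk6, Prss35, Fat3 and Prom1 had the lowest ratios within the naming limits, 52.5-fold, 19.4-fold, 12.4-fold, 12.1-fold and 11.5-fold lower. Fabp3 was among the leading genes of 1 of 5 control clusters of alveolar fibroblast-like cells, with 233 cells, and of none of the 3 mutant clusters, 1 of which had Smim41, Cdh11 and Sfrp1 among its leading genes, so these ratios cover different clusters. Of angiogenesis genes 12 of 27 were higher, with Nrp1 at 2.68, and Vegfa stood at -1.50. Immediate early genes were higher in 9 of 22 cases, with Klf4 at 3.24 and Hspa1a at 2.76. The collagen median of 0.21 was -0.15 with coarser clusters.

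Contractile RNA was lower over the whole class of myofibroblast or smooth muscle-like cells in the mutant, but unevenly between its clusters. Acta2 was at 4258 CPM in 2906 control cells and 1477 CPM in 1321 mutant cells, 2.88-fold (interval 2.84 to 2.93) lower, Tagln 2.10-fold (interval 2.07 to 2.13) and Actn1 3.20-fold (interval 3.03 to 3.39) lower, and 5 of 20 contractile genes were at least 2-fold lower (median -0.70). Values by cluster are on plain totals. Control cells came from 6 clusters, with Acta2 from 2282 to 6020 CPM, and mutant cells from 2. In 1 of these, with 665 cells and Actg2 and Tagln among its leading genes, Acta2 was at 2441 CPM and the contractile median against all control cells was -0.22, and in the other, with 656 cells and Cyp2e1, Wif1 and Notum among its leading genes, Acta2 was at 247 CPM and the median -1.93. Elastic fibre genes were lower in 5 of 19 cases (median -0.74), with Mfap5 at -2.88 and Mfap4 at -1.46. Cell division genes were lower in 16 of 25 cases (median -1.26), and Ccnd1, the cyclin D1 gene, was 18.4-fold (interval 14.4 to 23.99) lower, followed by Cd34 at 14.2-fold, Aard at 9.70-fold, Prr5l at 9.42-fold and Nnmt at 8.06-fold lower. Serpina3n was 1804-fold (interval 828 to 4918) higher, and Scara5, Zbtb16 and Cyp1b1 were 363-fold, 329-fold and 323-fold higher.

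Of p53 targets 5 of 17 were at least 2-fold higher and 2 lower in these myofibroblasts (median 0.42), with Cdkn1a 25.4-fold (interval 23.4 to 27.5) and Trp53inp1 7.73-fold (interval 7.28 to 8.20) higher. TNF and NF-kB genes were higher in 11 of 24 cases (median 0.97), with Icam1 at 2.12, and immediate early genes in 13 of 22 (median 1.16), with Atf3 at 2.43. The interferon-gamma response had 16 of 25 members higher and 1 lower (median 1.99), which was 0.85 after subtraction of free RNA. The angiogenesis median of 0.61 was -0.30 after that subtraction, while Pgf stood at 1.63, Vegfa at -1.15 and Unc5b at -2.27 before it. Endothelial RNA made up 0.607% of control and 1.97% of mutant UMIs in this class.

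**Figure D2:**
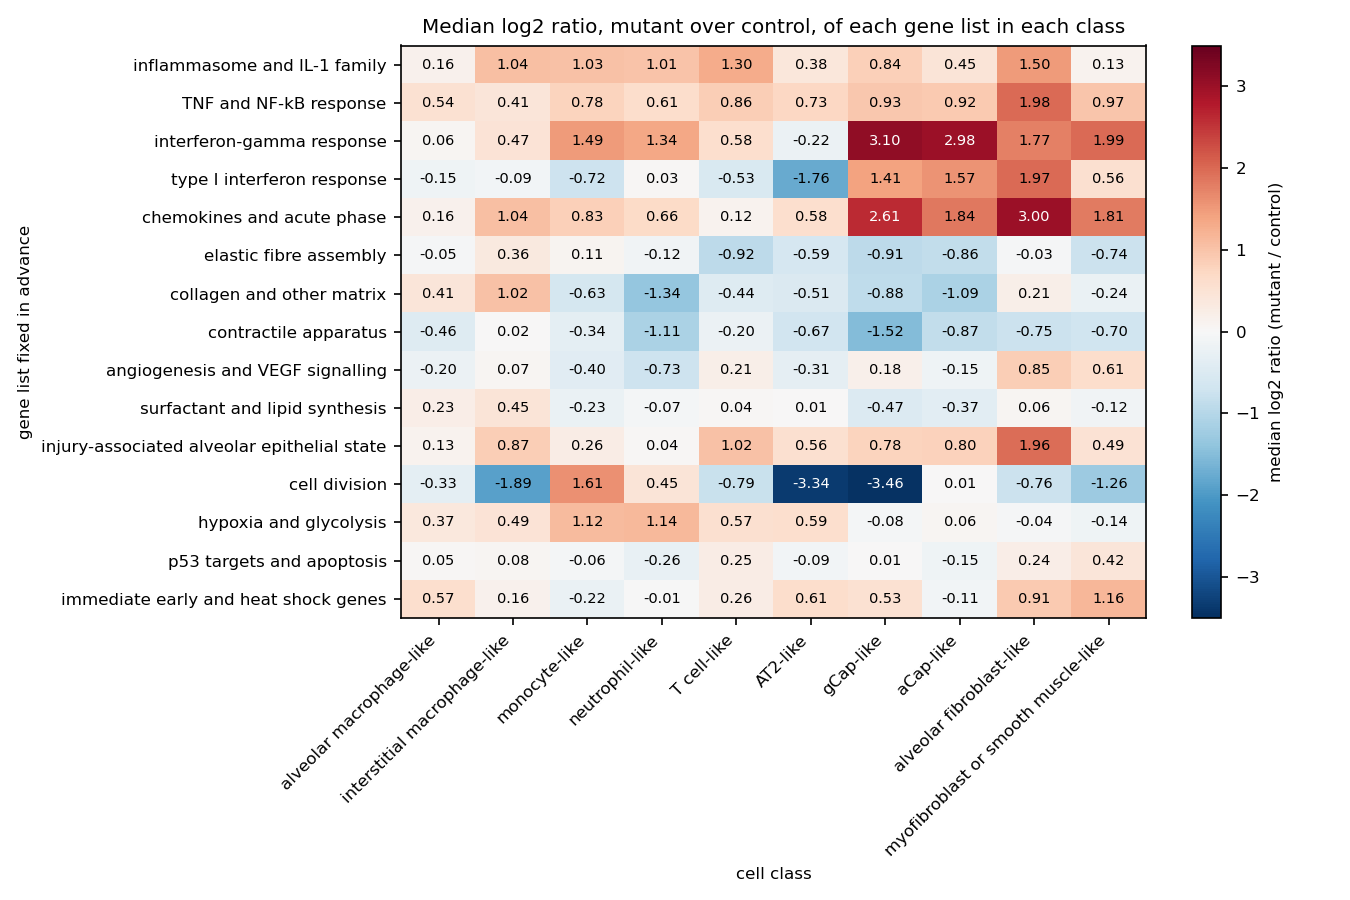
Median log2 ratio, mutant over control, of each of 15 gene lists (vertical axis) in each of 10 classes (horizontal axis), with the value printed in each square and red for higher in the mutant. The interferon-gamma list reached 3.10 in gCap-like and 2.98 in aCap-like cells, and the cell division list -3.46 in gCap-like and -3.34 in AT2-like cells.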

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

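The tests of sex below were chosen only after the result was seen. Transcripts outside the compared genes differed between the genotypes: Xist, which is made from the inactive X chromosome of females, was at 183.9 CPM in mutant library 3 and 677.5 CPM in mutant library 4, against 0.456 CPM and 0.129 CPM in control libraries 1 and 2. Summed transcripts of 4 Y-linked genes were at 145 and 183 CPM in control and at 44.4 and 93.8 CPM in the mutant libraries. Mutant cells with Xist and no Y transcripts made up 25.7% and 45.9% of libraries 3 and 4, those with Y transcripts and no Xist 11.6% and 25.4%, and those with both 8.09% and 4.75%.

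Sex of the pooled mice could therefore underlie differences between the genotypes. Over the 93 pairs of a list and a class whose median lay outside the middle 95% of random lists, the value in mutant cells with Y transcripts was a median of 0.845 of the value in all mutant cells (quartiles 0.594 to 1.23), and 89 of the 93 had the same sign. A whole cause by sex would have put that ratio under 0.5. Of the 93 pairs 60 reached 0.75 of the value in all mutant cells. In library 3, however, 1218 cells held both Xist and Y transcripts and 1743 held Y transcripts without Xist, against 516 and 2755 in library 4. Y transcripts therefore need not mark male cells in library 3. The ratio covers classes of libraries 3 and 4 together, so it cannot decide on sex, which stays open in whole or in part. Cells from mutant males and females came from the same libraries, so a difference between libraries cannot be told apart from genotype, and genotype itself stays open as untested.

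MHC class II genes went in opposite directions in 2 classes, and the difference between the classes was not tested. They were also far lower in interstitial macrophage-like cells, from the same libraries as AT2-like cells, while gCap-like cells came from other libraries. In AT2-like and gCap-like cells the log2 ratios were -5.56 and 5.74 for H2-Ab1, -4.88 and 7.15 for H2-Aa, -4.92 and 8.16 for H2-Eb1 and -3.49 and 8.18 for Cd74. Free RNA of B cells and dendritic cells, which were more common in the control library, could raise these genes in control AT2-like cells, but tracer genes of both predicted 23.2 of the 448 CPM of H2-Ab1 found there, or 5.19%, which argues against it. Interstitial macrophage-like cells were not among the sources traced for this. In mutant AT2-like cells with Y transcripts the median over the 4 genes was -5.97. These cells came from library 3, where Y transcripts need not mark male cells, so this value cannot decide on sex, which stays open. Genotype and a difference between libraries stay open, untested and not separable in this design.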

How the results depend on the processing

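Free RNA subtraction, the splits by Xist and Y transcripts, naming of low UMI clusters and the absence of scaling were chosen only after the result was seen. No paired analysis was possible because control replicates 1 and 2 and mutant replicates 3 and 4 share no numbers. DESeq2, an estimated correlation and leaving out each replicate were not run, since each class had 1 library per genotype. Of list medians 1462 of 1645 values moved within their limits (0.5 times the width of the middle 95% of random medians for lists, the exact 95% interval for genes and shares), 162 moved further and 21 turned direction; of ratios of the largest genes these were 946, 150 and 1 of 1097, and of share ratios 49, 21 and 2 of 72. All 100 named largest genes stayed at least 2-fold apart in 10 settings and 95 did with free RNA subtracted, which says little of stability since they were picked for size. List members at least 2-fold lower numbered 40 in place of 18 in alveolar macrophage-like and 67 in place of 44 in myofibroblast or smooth muscle-like cells with Y-bearing mutant cells, and 28 in the former with free RNA subtracted; without scaling neutrophil-like cells had 44 higher and 106 lower in place of 79 and 65, so the balance turned. With Y-bearing cells the medians of collagen in alveolar macrophage-like, interferon-gamma in interstitial macrophage-like, contractile in neutrophil-like and injury genes in aCap-like cells were -0.38, -0.33, 0.28 and -0.0094. With free RNA subtracted, surfactant stood at -0.081 in alveolar macrophage-like cells, chemokines, surfactant, glycolysis and Saa3 at -0.31, -0.40, -0.064 and -1.89 in interstitial macrophage-like cells, contractile at 0.45 in neutrophil-like cells and angiogenesis at -0.30 in myofibroblast-like cells; the subtracted RNA itself is the construction of these shifts. In neutrophil-like cells without scaling TNF stood at -0.15, chemokines at -0.10 and cell division at -0.30, by the shift left in; with all genes that had a count chemokines were at -0.23 and immediate early genes at 0.12, the latter also at 0.0604 with doublets kept, 0.0135 with Xist-bearing cells and 0.0012 with RLE, and thinning put contractile genes at 0.083. Injury genes in aCap-like cells were at -0.38 with all genes that had a count, and collagen in alveolar fibroblast-like cells at -0.15 with coarser clusters. Share ratios, mutant over control, with stricter cells were 0.481 for alveolar macrophage, 0.701 for interstitial macrophage, 0.220 for dendritic, 0.528 for T, 0.709 for gCap, 1.85 for aCap, 1.98 for alveolar fibroblast and 0.974 for adventitial classes. With doublets kept they were 0.587 for interstitial macrophage, 0.365 for monocyte, 0.711 for dendritic, 0.736 for T and 0.809 for ciliated classes. Coarser clusters gave 6.32 for neutrophil, a bound of 0.0160 with 0 mutant cells for dendritic, 1.18 for alveolar fibroblast and 2.17 for adventitial classes, and low UMI clusters named gave 1.005 for alveolar macrophage, 0.196 for monocyte, 3.78 for neutrophil, 0.245 for ciliated, 1.77 for alveolar fibroblast and 0.810 for myofibroblast classes. Except where stated the cause was not tested. Depth limits classes with few cells and folds resting on 1 to 5 control UMIs, whose intervals are wide.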

Other observations

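The tests of depth, sex and dilution below were chosen only after the result was seen, as were the splits into clusters and the genes named here from classes outside the main comparison. Venous-like endothelial cells, 250 in control and 275 in the mutant, held more of the leukocyte adhesion gene Selp, 45.3-fold (interval 27.3 to 81.3) higher, of Lrg1, 35.4-fold (interval 28.4 to 44.8) higher, and of the chemokine scavenger gene Ackr1, 638-fold (interval 114 to 25235) higher with 1 control UMI. Arterial-like cells held more of the tip cell gene Esm1, 19.9-fold (interval 14.4 to 28.5) higher, and a mutant cluster giving 671 cells of this class was led by Esm1 and Gja5. Interferon-gamma genes were at least 2-fold higher in 21 of 27 measured cases in arterial-like, 18 of 27 in venous-like and 12 of 27 in lymphatic-like cells, with 0 lower in each. Lymphatic-like cells had 23 of 26 cell division genes lower (median -3.69), with Mki67 at 203 CPM in control and 7.70 CPM in the mutant, and Lcn2 9.78-fold (interval 7.96 to 12.1) higher.

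Pericyte-like cells, 488 in control and 128 in the mutant, had 13 of 20 contractile genes at least 2-fold lower (median -1.58), but control cells included a cluster of 175 cells led by Map3k7cl, with Actc1 among its leading genes, with no such cluster among mutant pericyte-like cells. On plain totals the contractile median was -1.43 against all control cells and -0.37 against the other control cluster alone, of 313 cells. In the latter comparison Acta2 was at 922 CPM in control and 524 CPM in the mutant and Eln at 352 and 1889 CPM. Adventitial fibroblast-like cells held more Saa3, 110.1-fold (interval 92.9 to 131) higher, and Serpina3n, 25.1-fold (interval 22.9 to 27.7) higher. Cells like type 2 innate lymphoid cells had 21 of 26 cell division genes lower (median -2.69) with 33 mutant cells. Over all cells Mki67 and Top2a together were at 281 and 316 CPM in control libraries 1 and 2 and at 169.6 and 92.6 CPM in mutant libraries 3 and 4, but the mix of cells differed as well, with mesenchymal cells at 64.5% of named cells in library 2 and 32.5% in library 4.

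Cell division genes were lower in mutant AT2-like and gCap-like cells, with medians of -3.34 and -3.46, and 3 technical explanations were tested. Lower depth in the mutant could hide them, but its median UMIs per cell were 1.21 and 1.13 times those of control, which argues against it. RNA of other cells could dilute them, and the fixed markers of each class had medians of 0.037 and 0.65. Clusters were named by these same markers, so cells with strongly diluted markers could have stayed unnamed and the markers cannot decide on dilution. Dividing mutant cells may sit in unnamed clusters. Adding the unnamed dividing cluster of 365 cells to AT2-like cells left -1.80 in place of -3.34, which argues against that cluster as the whole cause and leaves a part open. Low UMI mutant clusters with AT2 genes among their leading genes, such as those of 3011 and 1050 cells, were not added. Adding 125 cells to gCap-like cells gave -0.56, so there it cannot be told apart from fewer divisions. Unnamed dividing control clusters of 292, 255 and 81 cells in library 2 were not added, nor was a control cluster of 186 cells in library 1 with histone genes among its leading genes. In mutant cells with Y transcripts the medians were -3.37 in AT2-like and -4.19 in gCap-like cells. These cells were taken from the named classes only, so the unnamed dividing clusters were again left out. In library 3, which held the AT2-like cells, Y transcripts also need not mark male cells. The medians therefore cannot decide on sex, which stays open. Genotype and a difference between libraries stay open for both classes, untested, as does RNA of dividing cells in the control libraries.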
